A study of Mus musculus with 10 samples.

How the data were processed

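The data are 2 tables of the whole series, 1 for mRNA and 1 for mature miRNAs, each with 5 columns, 2 from mice in natural light and 3 from mice under blue light. Columns were matched to samples by title and grouped by the source name, and no column was left unused. Per the labels' protocols, total RNA was extracted from eyeballs with Trizol, ribosomal RNA was removed with biotin-labelled probes, and the RNA was fragmented and primed at random. The submitters' processing notes name bcl2fastq 2.0, HISAT2, StringTie, DESeq2, limma and the build mm10, without roles, and which of them apply to the miRNA libraries is not given in the sources used here. The deposited mRNA values are taken as estimated counts per gene symbol, not normalised by the authors, since StringTie is named and the low values are uneven. Over all libraries 1051 values equal 4 and 1107 equal 5, against 751 equal to 3 and 580 equal to 6, as if 1 sequenced fragment added more than 1 unit. For that reason no counting intervals are given for mRNA, and the tests treat the estimated counts, which are whole numbers in the table so that rounding changes nothing, as counts. The deposited miRNA values are whole-number counts per mature miRNA, not normalised by the authors, and their counter is not given in the sources used here. Whether mRNA counting used strand is not stated either, so overlapping genes are uncertain. Of the 421 called genes, 411 had a position in the reference gene table (GRCm38, the assembly called mm10), and 114 of these shared a locus with another gene. With overlapping genes summed, 3 of the 114 reversed and 24 lost over 50 percent of their log2 fold change.

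Library totals ran from 87071487 to 107660103 units for mRNA and from 8355432 to 10875487 counts for miRNA. The 10 most abundant genes took 13.4% and 22.5% of control A and B and 18.9%, 16.9% and 22.7% of blue A, B and C. Spearman correlations between libraries ran from 0.980 to 0.989 for mRNA and from 0.905 to 0.914 for miRNA, and no pair of libraries was identical.

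Groups were compared in each assay with edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr by group, the quasi-likelihood F-test and Benjamini-Hochberg adjustment over all tested genes, with a threshold of 0.05. The letters A, B and C were not used as a block. Lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, 2-sided, adjusted over all lists of an assay with at least 3 tested members. Of 37 mRNA lists 36 were tested, because none of 13 mitochondrially encoded genes matched a symbol, and of 14 miRNA lists 13 were tested, because the endothelial list had 2 tested members. Camera was repeated with the correlation estimated from the data, and fry tested whether a list's genes move, on balance, one way. Called mRNA lists numbered 12 and called miRNA lists 2 with the preset correlation, and 0 in both assays with the estimated one, where 2 mRNA lists and 0 miRNA lists had an unadjusted p under 0.05 and fry called 1 and 0.

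Groups, tests, lists, the named-gene rule and most alternatives were fixed before the data were examined. The rule named the 10 raised and 10 lowered mRNAs with the smallest p that passed and whose groups did not overlap, without symbols of the Gm or Rik form. For miRNAs it named 6 and 6, or, with fewer than 5 passing in a direction, the 5 with the smallest p in it. It also named up to 4 members with the smallest p of each list described, and 10 mRNAs and 7 miRNAs whatever their values. Some of the genes it named are not reported here. Members of the rod and gliosis lists beyond these 4 (Nrl, Pde6a, Pde6b, Rp1, Rcvrn, Lcn2, Stat3, Cebpd, Osmr and A2m), Nudt6, Hba-a2 and the photoreceptor cilium genes were named after their values were seen.

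Alternatives were DESeq2's size factors in edgeR, library totals as the only scaling, scaling without lens, muscle and red blood cell genes, no low-count filter, a mean CPM of at least 5, DESeq2 1.42.0 (Wald test), limma-voom, an absolute log2 fold change of at least 1, the letter as a replicate block, and leaving out each library in turn. Where that left 1 control, the lone library was assumed to vary like the blue libraries. Chosen after seeing the data were mRNA values divided by 4, overlapping genes summed into loci, and the Rn45s share or the muscle list level as a covariate.

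The pipeline was tested on simulated counts drawn from the real means, dispersions and library sizes. For mRNA, 200 of 18988 genes were changed, and a second low-count filter left 18650 genes. Of the changed genes that passed this filter, 46.9% were recovered at 2-fold and 67.0% at 4-fold. Of the calls, 11.3% were unchanged genes, above the nominal 5 percent. For miRNA, 60 of 641 were changed, and the second filter left 622 miRNAs. Among the changed miRNAs that passed it, 40.0% were recovered at 2-fold and 96.3% at 4-fold, and 9.52% of calls were unchanged. Changed genes or miRNAs lost to the second filter do not count in these recovery shares. Of 20 lists drawn from unchanged genes, 0 passed camera in either assay. These draws hold no correlation between genes, so they say nothing of lists whose genes vary together.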

Results

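RNA from eyeballs of female Kunming mice, an outbred stock labelled as 4 weeks old, was sequenced in 5 mRNA libraries and 5 miRNA libraries. In each assay 2 libraries came from animals kept in natural light (control A and B) and 3 from animals kept under an 18 W blue lamp in a dark container (blue A, B and C). The sample titles carry day 14. The deposited mRNA table held 24736 gene symbols, of which 3340 were at 0 in every library. Its estimated counts summed to 107660103 in control A, 87071487 in control B, 99253431 in blue A, 102602360 in blue B and 93202801 in blue C. The miRNA table held 1978 mature miRNAs, and its counts summed to 8355432 and 9442889 in the controls and to 10875487, 10444317 and 8860154 in blue A, B and C. The labels do not say that the libraries of a group came from separate animals, so the p-values measure only the spread between these samples, which may be technical. An eyeball sample holds retina, lens, cornea and attached tissue together, and every level below is an average over them. Log2 fold changes (log2FC) are blue light minus natural light. Their standard error (SE) in edgeR is the absolute log2FC divided by the square root of the test's F statistic. It restates that test and is no separate estimate of spread. Levels are TMM-normalised counts scaled to a common library total (CPM) as mean ± SD, with n = 2 control and n = 3 blue libraries. Adjusted p-values of genes come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

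The first comparison asked which mRNAs differ between eyes under blue and under natural light. Of 24 genes of rod photoreceptors, the cells of dim-light vision, 20 fell. Of 16 genes listed for the glial stress response 15 rose, and in which cells of the eyeball they rose was not tested. Guca1b, a calcium sensor of photoreceptors on chromosome 17 from 47384694 to 47392967 (mm10), fell by 1.98 on the log2 scale (SE 0.17, adjusted p = 0.0157), from 308 ± 25.5 to 78.1 ± 15.6 CPM. Gfap, the intermediate filament of reactive glia on chromosome 11 from 102887336 to 102897200, rose by 3.17 (SE 0.20, adjusted p = 0.0118), from 15.4 ± 3.71 to 139 ± 18.9 CPM. Of 18988 genes tested, 421 passed the threshold, 126 higher and 295 lower under blue light, and 65 of the higher and 133 of the lower genes changed at least 2-fold. All 421 had groups that did not overlap, as did 35.6% of all tested genes against 20% by chance. DESeq2 called 1729 genes, among them all 421. With library totals as the only scaling, 124 genes were higher and 150 lower, which put the higher share at 45.3% in place of 29.9%. With 1 library fewer in the fit the count was 8 without control A, 311 without blue A, 277 without blue B, 11 without blue C and 0 in edgeR without control B, where 2872 genes had an unadjusted p under 0.05. With the Rn45s share, chosen after the results were seen, as a covariate it was 0 in edgeR, with 2510 genes at an unadjusted p under 0.05. In each of these fits all 421 kept their sign, but they were picked in these same libraries, so this is no independent support.

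Of the 10 raised genes with the smallest p, 7 belong to the reactive gliosis list. Ceruloplasmin (Cp), a copper-binding ferroxidase, rose by 1.42 (SE 0.076), from 188 ± 9.02 to 506 ± 19.2 CPM. The sphingosine-1-phosphate receptor S1pr3 rose by 1.25 (SE 0.074), and the cytokine signalling inhibitor Socs3 by 2.92 (SE 0.18). Endothelin 2 (Edn2), a peptide released by stressed photoreceptors, rose by 4.34 (SE 0.33), from 2.64 ± 1.20 to 53.8 ± 7.63 CPM. The growth factor Fgf2 rose by 2.94 (SE 0.23). Its annotated span on chromosome 3 (37348477 to 37410106) overlaps that of Nudt6 (37404982 to 37420242), which also rose, by 1.98 (SE 0.26), and without stated strand their counts could be shared. The CPM of the pair summed to 6.89 and 6.14 in the controls and to 26.2, 40.6 and 36.9 in blue A, B and C. With all 3 overlapping genes of that locus summed, an alternative chosen after the results were seen, the log2FC was 1.03 (adjusted p = 0.0245 in edgeR). Bcl3, a nuclear partner of NF-kB, rose by 3.03 (SE 0.22), the protease inhibitor Serpina3n by 2.33 (SE 0.18), the cytokine receptor kinase Jak3 by 1.54 (SE 0.12) and the secreted factor Ndnf by 0.93 (SE 0.067). Adjusted p of these genes lay between 0.0115 and 0.0137 in edgeR.

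Of the 10 lowered genes with the smallest p, Reep6, an endoplasmic reticulum protein of rods, fell by 1.85 (SE 0.13), from 374 ± 37.5 to 104 ± 14.3 CPM. Rabgef1, an exchange factor for endosomal Rab5, fell by 1.87 (SE 0.11), from 182 ± 15.5 to 49.8 ± 5.53 CPM, and the ecto-5'-nucleotidase Nt5e by 1.54 (SE 0.12). The collagen gene Col19a1 fell by 2.04 (SE 0.11), Igsf9 by 1.20 (SE 0.066), the inhibitor of Fas-mediated cell death Faim by 1.08 (SE 0.070), the inositol kinase Ip6k2 by 1.05 (SE 0.070) and the ubiquitin ligase Rnf123 by 1.04 (SE 0.080). The long noncoding gene BB283400 on chromosome 6 (30176623 to 30178046) fell by 1.82 (SE 0.12). Moap1 stood at 14.3 ± 2.16 CPM in the controls and 0.0584 ± 0.0300 CPM in the blue libraries, with a log2FC of -7.93 (SE 0.37). Its span on chromosome 12 (102739830 to 102743661) lies within that of Gm20604 (102739830 to 102757810), which was chosen after its values were seen and rose by 1.45 (SE 0.16). The CPM of the pair summed to 22.8 and 22.2 in the controls and to 21.0, 23.6 and 22.9 in blue A, B and C, so the value of Moap1 alone is uncertain. Adjusted p of the 10 genes lay between 0.0115 and 0.0137 in edgeR.

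**Figure D1:**
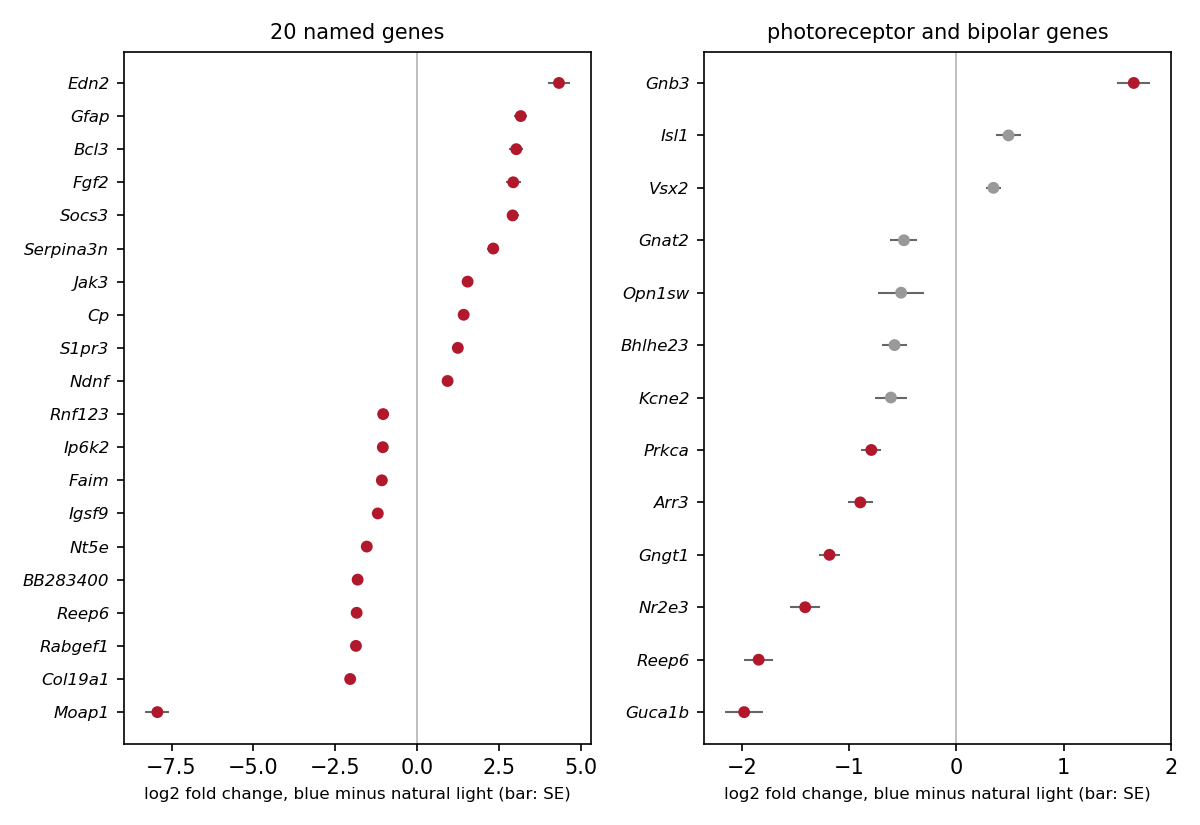
Log2 fold change of blue against natural light for the 10 genes with the smallest p in each direction (left) and for named rod, cone and bipolar cell genes (right), with bars of 1 SE and n = 2 control and 3 blue libraries. Red points passed an adjusted p of 0.05 and grey points did not; Gnb3 lies at 1.65 and Guca1b at -1.98, and Moap1 shares its locus with Gm20604.

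Every one of the 24 rod genes had a negative log2FC, and 20 fell in the test over all genes. Adjusted over the list alone, 24 fell. The median log2FC was -1.53, a 2.89-fold lower level, and the list passed camera, limma's test of a list against the other genes, at an adjusted p of 6.54e-22 with the preset correlation. It did not pass with a correlation estimated from these libraries (adjusted p = 0.834 with an estimated correlation), nor in fry (fry adjusted p = 0.0820). The rod transcription factors Nrl (-2.08) and Nr2e3 (-1.41) were among the genes that fell, as were Guca1b, the transducin subunit Gngt1 (-1.18) and the phosphodiesterase subunit Pde6b (-2.03). Pde6a, its partner subunit, had a log2FC of -0.95 and an adjusted p of 0.140. The list's level, the mean over its members of log2 CPM after subtracting each member's mean over the 5 libraries, was 1.01 and 0.90 in control A and B and -1.01, -0.32 and -0.58 in blue A, B and C.

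The lists of other retinal neurons did not pass. Among 15 cone genes 1 rose and 1 fell over all genes, and adjusted over the list alone 1 rose and 4 fell; the median log2FC was -0.18 and the camera adjusted p 0.576. The cone arrestin Arr3 fell by 0.90 (SE 0.12), while the transducin subunit Gnb3, which cones share with ON bipolar cells, rose by 1.65 (SE 0.15), from 92.2 ± 9.36 to 290 ± 43.0 CPM. The short-wave opsin Opn1sw stood at 200 ± 32.1 CPM in controls and 140 ± 36.2 CPM in blue libraries (log2FC -0.52, adjusted p = 0.322). Of 16 bipolar cell genes 1 fell, protein kinase C alpha (Prkca), by 0.79 (SE 0.093); the list median was 0.12, the camera adjusted p 0.487, and adjusted over the list alone 4 rose and 2 fell. None of 16 amacrine and horizontal cell genes passed in edgeR (median -0.0074, camera adjusted p = 0.823), where 2 had an unadjusted p under 0.05 in each direction, DESeq2 called 3 and limma-voom 0; adjusted over the list alone 2 rose and 1 fell. None of 15 ganglion cell genes passed either, with 1 at an unadjusted p under 0.05 and 0 calls in DESeq2, in limma-voom or adjusted over the list alone. Their median was -0.017, although camera ranked the list upward (adjusted p = 0.744). Of 25 synapse genes 1 fell, the photoreceptor calcium channel Cacna1f, by 1.07 (SE 0.13); the list median was -0.10, the camera adjusted p 0.222, and adjusted over the list alone 1 rose and 2 fell.

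Reactive gliosis, the stress program of Muller glia and astrocytes, was the raised list with the smallest p. Of its 16 genes 15 rose, and adjusted over the list alone 15 rose. The median log2FC was 2.31, a 4.95-fold higher level. The camera adjusted p was 4.37e-22, and the list did not pass with the correlation estimated (adjusted p = 0.275 with an estimated correlation). In fry it was the only mRNA list to pass (fry adjusted p = 0.00372). The lipocalin Lcn2 rose by 4.62, the transcription factors Stat3 and Cebpd by 1.31 and 2.55, and the receptor Osmr by 1.34 (Cebpd 1.74 with the gene it overlaps summed), whereas A2m had a log2FC of 0.27 (adjusted p = 0.337). The list stood at -1.34 and -1.30 in the controls and at 0.84, 0.97 and 0.83 in blue A, B and C. Of 14 genes of resting Muller glia 3 rose: Cp, the glutamate transporter Slc1a3 by 0.87 (SE 0.074) and clusterin (Clu) from 671 ± 24.4 to 1342 ± 131 CPM (SE of the log2FC 0.11). Glutamine synthetase (Glul) had a log2FC of -0.48 (adjusted p = 0.0537). The list median was 0.40 and the camera adjusted p 0.000226 (adjusted p = 0.834 with an estimated correlation), and adjusted over the list alone 8 rose and 1 fell.

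**Figure D2:**
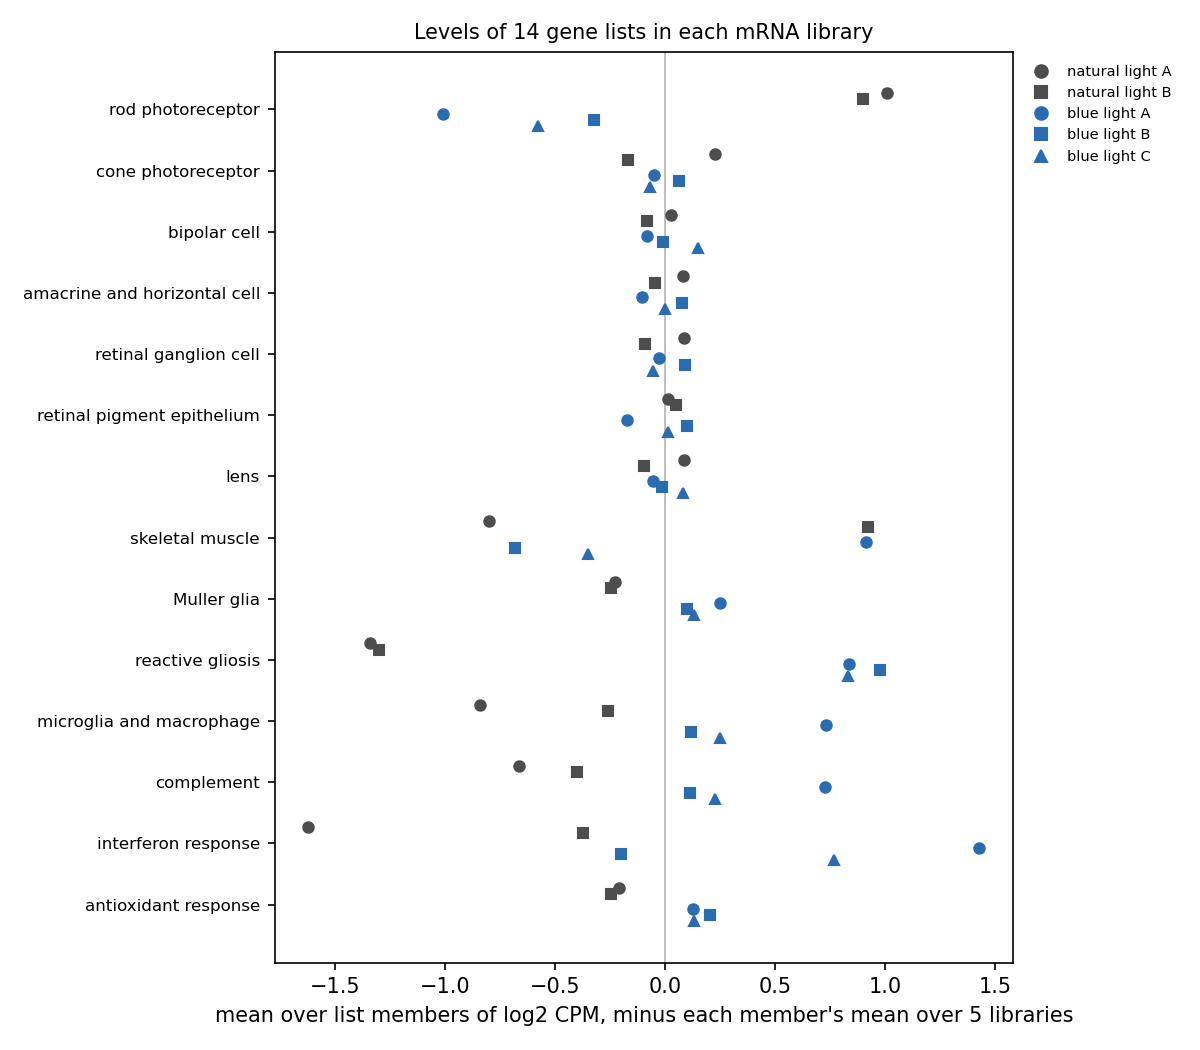
Level of 14 gene lists in each of the 5 mRNA libraries, as the mean over list members of log2 CPM minus each member's mean over the libraries; each point is 1 library, grey for natural and blue for blue light, with the shape giving the letter. Rods lie at 1.01 and 0.90 in the controls and between -1.01 and -0.32 under blue light, reactive gliosis at -1.34 and -1.30 and between 0.83 and 0.97, while skeletal muscle spans both groups.

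The microglia and macrophage, interferon, complement, and cytokine and NF-kB lists passed camera upward with the preset correlation and not with an estimated one (adjusted p = 0.912 for each with an estimated correlation), and antigen presentation and neutrophil genes did not pass. The 20 microglia and macrophage genes had a median log2FC of 0.93 and passed camera at an adjusted p of 2.46e-08 (adjusted p = 0.912 with an estimated correlation). Their level was -0.84 and -0.26 in control A and B and 0.73, 0.12 and 0.25 in blue A, B and C. In edgeR 0 of them passed over all genes, with 12 at an unadjusted p under 0.05, 11 calls in DESeq2 and 1 in limma-voom, and adjusted over the list alone 11 rose. The cathepsin Ctss stood at 19.0 ± 8.97 against 72.7 ± 19.1 CPM (log2FC 1.94, adjusted p = 0.0649), with Trem2 at 1.73 (0.0631), C1qc at 1.22 (0.0622) and Csf1r at 0.78 (0.0661). The 20 interferon-stimulated genes had a median of 1.76, all with a positive log2FC, and passed camera at an adjusted p of 1.66e-07 (adjusted p = 0.912 with an estimated correlation). In edgeR 0 passed over all genes, with 14 at an unadjusted p under 0.05, 9 calls in DESeq2 and 0 in limma-voom, and adjusted over the list alone 12 rose. Mx2 had a log2FC of 2.78 (SE 0.73, adjusted p = 0.142), Ifit1 2.51 (SE 0.69, adjusted p = 0.157), Usp18 2.50 (SE 0.63, adjusted p = 0.134) and Irf9 1.43 (SE 0.36, adjusted p = 0.136). The interferon level was -1.62 and -0.37 in control A and B and 1.43, -0.20 and 0.77 in blue A, B and C. Beside it the skeletal muscle level was -0.80 and 0.92 in the controls and 0.91, -0.68 and -0.35 in the blue libraries. The level of adipocyte genes, markers of another tissue, was -0.85 and -0.61 in the controls and 1.03, -0.38 and 0.80 in the blue libraries, in the same order over the 5 libraries as the interferon, microglia and macrophage, complement, cytokine and NF-kB, and autophagy levels. The interferon median was 2.71 without control B and 1.20 without control A, and the call held in both.

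Of 14 complement genes 2 rose, Cfi by 5.30 (SE 0.53) from 0.246 ± 0.0333 to 9.79 ± 4.66 CPM and C4b by 2.33 (SE 0.36) from 85.9 ± 33.1 to 432 ± 125 CPM. C3 had a log2FC of 1.77 (adjusted p = 0.0707). DESeq2 called 5 genes of this list higher and limma-voom 1. The list median was 0.47, the camera adjusted p 0.00243 (adjusted p = 0.912 with an estimated correlation), and adjusted over the list alone 4 rose; the median was 0.26 without blue A. The complement level was -0.66 and -0.40 in the controls and 0.73, 0.11 and 0.22 in blue A, B and C, in the same order as the adipocyte level. Among 22 cytokine and NF-kB genes the adhesion molecule Vcam1 rose by 0.96 (SE 0.13), and Tnfaip3, an inhibitor of NF-kB signalling, fell by 1.95 (SE 0.19), from 124 ± 30.5 to 32.2 ± 4.91 CPM. The chemokine Ccl12 had a log2FC of 2.23 (adjusted p = 0.0613) and Icam1 0.65 (adjusted p = 0.0968). That list had a median of 0.59 and a camera adjusted p of 0.000315 (adjusted p = 0.912 with an estimated correlation), and adjusted over the list alone 4 rose and 1 fell. Without control A its median was 0.14 and its adjusted p 0.158. Its level was -0.74 and 0.025 in the controls and 0.44, 0.12 and 0.16 in blue A, B and C, also in the order of the adipocyte level. The 15 antigen presentation genes missed the threshold (median 0.36, camera adjusted p = 0.0514). In edgeR 0 of them passed, over all genes or adjusted over the list alone, with 1 at an unadjusted p under 0.05 (H2-K1, log2FC 0.96), 1 call in DESeq2 and 0 in limma-voom. The 7 neutrophil genes tested had a median of 0.51 and a camera adjusted p of 0.487; 0 passed in edgeR, with 1 at an unadjusted p under 0.05 in each direction, 1 call in DESeq2 and 0 in limma-voom, and adjusted over the list alone 1 rose.

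Of 24 antioxidant genes 4 rose: the plasma glutathione peroxidase Gpx3 by 2.21 (SE 0.24), from 54.2 ± 0.444 to 251 ± 65.3 CPM, the cystine transporter Slc7a11 by 0.98 (SE 0.090), and the metallothioneins Mt1 and Mt2 by 1.15 (SE 0.12) and 1.18 (SE 0.17). The heme oxygenase Hmox1 stood at 35.4 ± 37.5 against 75.9 ± 26.8 CPM (log2FC 1.10, adjusted p = 0.553). The list median was 0.19, the camera adjusted p 0.000226 (adjusted p = 0.834 with an estimated correlation), and adjusted over the list alone 6 rose; the median was 0.28 without control B. In the 23 p53 and apoptosis genes Gadd45b rose by 1.08 (SE 0.16). That list had a median of 0.20 and a camera adjusted p of 0.0107 (adjusted p = 0.899 with an estimated correlation), and adjusted over the list alone 2 rose. Its adjusted p was 0.0574 without control B and 0.0813 without blue B, and its median was 0.13 without blue A. The 18 immediate early genes had a median of 0.30 and a camera adjusted p of 0.0243 (adjusted p = 0.912 with an estimated correlation). In edgeR 0 of them passed, over all genes or adjusted over the list alone, with 6 at an unadjusted p under 0.05, 4 calls in DESeq2 and 0 in limma-voom. Egr2 had a log2FC of 1.40 (adjusted p = 0.0820), Egr1 1.53 (adjusted p = 0.221) and Junb 0.83 (adjusted p = 0.126). Without control A, blue A or blue B the list's adjusted p was 0.435, 0.157 or 0.0811, with the muscle level as a covariate it was 0.0674, and its median was 0.17 without blue A, 0.46 without control B and 0.47 without blue C.

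Markers of other eye tissues were also fixed as lists. Of 12 adipocyte genes 1 rose, adipsin (Cfd), by 2.55 (SE 0.42), from 0.304 ± 0.0240 to 1.79 ± 0.574 CPM. Cidec was at 0 in both controls and at 0.847 ± 0.688 CPM in the blue libraries, and leptin (Lep) at 0 and 0.233 ± 0.216 CPM. The adipocyte median was 0.69. Setting Cidec and Lep to the bound that 3 counts over both controls together allow (53.3-fold and 14.6-fold) could not move it, since both bounds lay far above it. The camera adjusted p was 0.00258 (adjusted p = 0.912 with an estimated correlation). Adjusted over the list alone 3 rose, and DESeq2 called 3 and limma-voom 0. Without control A the list's adjusted p was 0.0506, and without blue A its median was 0.43. The 10 melanin synthesis genes had a median of 0.19 and a camera adjusted p of 0.0442 (adjusted p = 0.912 with an estimated correlation). In edgeR 0 of them passed, over all genes or adjusted over the list alone, with 1 at an unadjusted p under 0.05 (Tyr, log2FC 0.35), 1 call in DESeq2 and 0 in limma-voom. Without control A, blue B or blue C that list's adjusted p was 0.697, 0.169 or 0.193, with the muscle level as a covariate it was 0.0870, and its median was 0.057 without control A, 0.35 without control B and 0.29 without blue A.

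Lens, cornea, pigment epithelium, stroma and muscle did not pass as lists. The lens crystallin Cryaa stood at 10908 ± 923 CPM in controls and 10502 ± 707 CPM in blue libraries (log2FC -0.055, SE 0.11, adjusted p = 0.859). The corneal keratin Krt12 stood at 1982 ± 157 and 2071 ± 214 CPM (log2FC 0.063, adjusted p = 0.844), and the visual cycle isomerase Rpe65 at 179 ± 17.9 and 165 ± 35.6 CPM (log2FC -0.11, adjusted p = 0.824). The muscle actin Acta1 stood at 97.8 ± 57.1 and 94.3 ± 40.0 CPM (log2FC -0.052, SE 0.46, adjusted p = 0.972). Median log2FC and camera adjusted p were 0.037 and 0.487 for lens, -0.084 and 0.581 for retinal pigment epithelium, 0.13 and 0.487 for ocular surface epithelium, -0.074 and 0.581 for stroma, and -0.11 and 0.964 for skeletal muscle. Over all genes 0 of the 113 members tested passed in edgeR, with 7 at an unadjusted p under 0.05, 3 calls in DESeq2 and 0 in limma-voom; adjusted over the list alone 1 fell. The alpha globin Hba-a1 (log2FC -0.0046, SE 2.75) is uncertain because counting could split reads between it and its near-identical copy Hba-a2. Hba-a1 stood at 21.0 and 0 CPM in control A and B and at 31.6, 0 and 0.0110 CPM in blue A, B and C, and Hba-a2 at 5.58 and 67.1 CPM and at 0, 29.8 and 31.3 CPM. The clock gene Arntl fell by 0.67 (SE 0.089, adjusted p = 0.0281), from 73.0 ± 3.86 to 45.8 ± 3.17 CPM. It was the only one of 20 clock genes to pass over all genes; adjusted over the list alone 2 rose and 1 fell, and the list had a median of -0.00092 and a camera adjusted p of 0.744. The share of counts on Rn45s, the ribosomal RNA precursor, was 4.30% and 14.1% in control A and B and 10.8%, 8.69% and 14.4% in blue A, B and C.

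The second comparison asked the same of mature miRNAs. Arms of miR-183 and miR-96, which share with miR-182 a cluster abundant in photoreceptors, fell, and both arms of miR-146b, a miRNA induced through NF-kB and STAT signalling, rose. The arm mmu-miR-183-5p fell by 1.13 (SE 0.16, adjusted p = 0.00945), from 101771 ± 6878 to 46503 ± 7529 CPM, and mmu-miR-96-3p by 1.26 (SE 0.19, adjusted p = 0.0109), from 32.5 ± 0.688 to 13.5 ± 1.32 CPM. The arm mmu-miR-146b-5p rose by 1.63 (SE 0.21, adjusted p = 0.00945), from 799 ± 43.3 to 2475 ± 547 CPM, and mmu-miR-146b-3p by 2.31 (SE 0.33, adjusted p = 0.00945), from 1.40 ± 0.378 to 6.89 ± 0.663 CPM. These were the 4 of 641 tested miRNAs that passed in edgeR, where 76 had an unadjusted p under 0.05. DESeq2 called 11 and limma-voom 4. All 4 had groups that did not overlap, as did 28.4% of tested miRNAs against 20% by chance. In edgeR 0 miRNAs passed without control A, without control B or without blue B, with 31, 90 and 47 at an unadjusted p under 0.05.

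Other miRNAs did not pass. In the rising direction the next smallest p belonged to mmu-miR-140-3p (log2FC 0.66, adjusted p = 0.137), mmu-miR-29a-5p (1.14, adjusted p = 0.180) and mmu-miR-146a-5p (0.82, adjusted p = 0.276). In the falling direction it belonged to mmu-miR-5100 (-1.47, adjusted p = 0.0596), mmu-miR-182-3p (-0.86, adjusted p = 0.0705) and mmu-miR-6538 (-1.37, adjusted p = 0.0860). The neuronal mmu-miR-124-3p had a log2FC of -0.44 (adjusted p = 0.276), the lens and corneal mmu-miR-184-3p -0.19 (adjusted p = 0.719), the pigment epithelium mmu-miR-204-5p 0.050 (adjusted p = 0.901), the muscle mmu-miR-1a-3p 0.42 (adjusted p = 0.544) and the erythroid mmu-miR-451a 0.073 (adjusted p = 0.904). With library totals as the only scaling the median of all miRNAs lay at 0.17, against 0.014 with TMM.

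All 6 arms of the miR-183 cluster had a negative log2FC, with a median of -0.87, a 1.83-fold lower level. Over all miRNAs 2 fell, and adjusted over the list alone 6 fell. The camera adjusted p was 1.02e-07, and the list did not pass with the correlation estimated (adjusted p = 0.749 with an estimated correlation). The 6 arms took 20.1% and 18.8% of counts in control A and B and 8.42%, 12.3% and 12.4% in blue A, B and C. In the mRNA libraries the annotated host Mirc35hg, chosen after its values were seen, lies on chromosome 6 from 30158640 to 30174125, around Mir182, Mir96 and Mir183. It fell by 1.34 (SE 0.14, adjusted p = 0.0191), from 34.5 ± 3.07 to 13.7 ± 1.88 CPM, and BB283400 next to it fell by 1.82. Of 11 leukocyte and inflammatory miRNAs mmu-miR-146b-5p rose, also when adjusted over the list alone, where 1 rose. That list had a median of 0.52 and a camera adjusted p of 0.0114 (adjusted p = 0.749 with an estimated correlation). Without control A its median was 0.12 and its adjusted p 0.573, without blue A 0.33 and 0.119, and without control B its median was 1.12; with library totals as the only scaling its adjusted p was 0.0633.

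**Figure D3:**
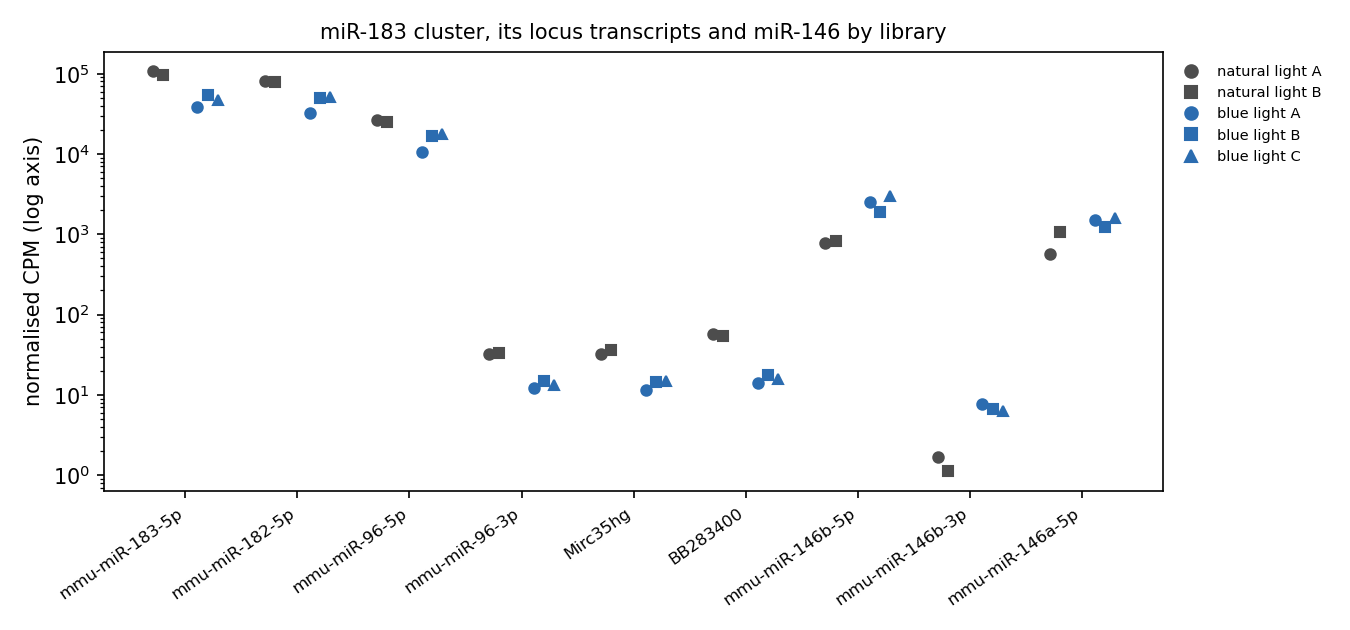
Normalised CPM on a log axis of miR-183 cluster arms, the locus transcripts Mirc35hg and BB283400, and miR-146 arms in each library, grey for natural and blue for blue light; miRNAs come from the miRNA libraries and the transcripts from the mRNA libraries. For mmu-miR-183-5p the group means are 101771 and 46503 CPM, and for mmu-miR-146b-5p they are 799 and 2475 CPM.

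The other 11 miRNA lists with at least 3 members tested did not pass. Median log2FC and camera adjusted p were -0.091 and 0.115 for neuronal miRNAs, 0.29 and 0.0559 for mesenchymal, 0.44 and 0.115 for the miR-17-92 clusters, 0.26 and 0.150 for the miR-29 family, -0.084 and 0.160 for the Dlk1-Dio3 cluster, and 0.15 and 0.344 for epithelial and corneal miRNAs. They were 0.088 and 0.306 for p53 and hypoxia miRNAs, 0.020 and 0.568 for muscle, 0.036 and 0.653 for the let-7 family and -0.064 and 0.653 for pigment epithelium miRNAs. The 2 endothelial arms tested, too few for a list test, had a median of 0.030. The 3 erythroid miRNAs had a median of 0.073, although camera ranked them downward (adjusted p = 0.810). In edgeR 0 of the 130 members tested passed over all miRNAs, with 20 at an unadjusted p under 0.05, 1 call in DESeq2 and 0 in limma-voom; adjusted over the list alone 1 rose and 1 fell.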

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

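The mRNA values divided by 4, summed loci and covariate fits were chosen after the results were seen; the other alternatives were planned. All 421 mRNA calls kept their sign in every gene-level alternative that measured them. In fits with at least 2 libraries per group they also kept an unadjusted p under 0.05. They were picked for small p in these same libraries, so this is no independent support. The number of calls was 373 with DESeq2's size factors, 422 with the reduced scaling set, 393 with no filter and 511 with a mean CPM of at least 5. The number was 457 in limma-voom, 483 with division by 4 and 420 with summed loci. It was 274 with library totals, 1729 in DESeq2, 843 with the muscle covariate and 0 with the Rn45s covariate in edgeR, where 2510 genes had an unadjusted p under 0.05; the cause was not tested. A minimum log2 fold change of 1 left 198 by its construction. Leaving out 1 library left fewer samples in each fit. That alone does not set the count, which at equal size was 311 without blue A, 277 without blue B and 11 without blue C. For miRNAs it was 32 without a filter and 11 in DESeq2, 3 to 4 in the other unblocked fits of all 5 libraries, and 0 to 6 without 1 library. Called mRNA lists fell from 12 to 0 with the estimated correlation and 1 in fry, and ran from 10 to 17 without 1 library. Called miRNA lists fell from 2 to 0 with the estimated correlation, 0 in fry and 1 with library totals, and ran from 2 to 6 without 1 library. Division of the mRNA values by 4 did not lower the number of calls, and since no such division was run for miRNAs, what depth limits there was not tested.

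The labels do not say that the letters pair the samples. Deviations from the group mean correlated at -0.18 and -0.15 for letters A and B in mRNA, and at -0.038 and -0.11 in miRNA. With n = 2 controls the deviations of control A and B mirror each other, so these values cannot show whether the letters pair samples. With the replicate block 0 mRNAs passed in edgeR (1455 at an unadjusted p under 0.05) and 9 miRNAs, and 11 mRNA and 2 miRNA lists, without melanin synthesis (camera adjusted p = 0.103); the immediate early median was 0.47. The replicate block turned the sign of 4 named non-passing genes, to 0.21 for Acta1, 0.58 for Hba-a1, -0.030 for mmu-miR-204-5p and -0.10 for mmu-miR-451a.

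Signs also turned for genes that did not pass, whose log2 fold changes lay between -0.11 and 0.073 in the planned test. Over fits without 1 library Rpe65 ran from -0.28 to 0.025 (without blue A), Cryaa from -0.14 to 0.060 (without control A; 0.0087 without blue B), Acta1 from -0.53 to 0.72 (without control B), Hba-a1 from -1.0 to 12.97 (without control A), mmu-miR-204-5p from -0.029 (without blue C) to 0.11 and mmu-miR-451a from -0.097 (without blue C) to 0.26. Acta1 was 0.029 with library totals, 0.025 in limma-voom, 0.081 with the muscle covariate, 0.11 without blue B and 0.14 without blue C. Hba-a1 was 0.0098 at a mean CPM of at least 5, 10.95 with the Rn45s covariate, 0.59 without blue B and 0.58 without blue C. The arm mmu-miR-451a was also -0.079 without control B. No value was obtained for Hba-a1 in DESeq2 or without blue A, nor for Cfd, mmu-miR-146b-3p and mmu-miR-29a-5p at a mean CPM of at least 5.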

Other observations

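The tests on retina content, scaling, muscle, single libraries and the Moap1 locus were chosen after the results were seen, as were the departures of rod genes from their list. The test on other splits was not. The prediction on cilium genes was written in advance of its own test. Its list was not among the 37 fixed mRNA lists, and it refers to the rod result.

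None of the 11 mRNA lists not described above passed camera. Ctsd, a lysosomal protease of the autophagy list, rose by 0.60 (SE 0.10), the mitochondrial iron carrier Slc25a37 of the red blood cell list by 0.90 (SE 0.14), and Atf4, a transcription factor of the unfolded protein response, fell by 0.43 (SE 0.072). Median log2 fold change and camera adjusted p were 0.014 and 0.487 for autophagy, 0.043 and 0.509 for red blood cells and 0.090 and 0.475 for the unfolded protein response. They were -0.11 and 0.475 for smooth muscle, 0.26 and 0.487 for orbital gland, 0.092 and 0.222 for myelin, 0.038 and 0.581 for heat shock, 0.054 and 0.506 for angiogenesis and hypoxia, 0.12 and 0.581 for cell cycle and -0.056 and 0.581 for glycolysis. Oxidative phosphorylation had a median of -0.00057, although camera ranked it upward (adjusted p = 0.714). In the 8 lists with 0 calls over all genes in edgeR, 15 members had an unadjusted p under 0.05, DESeq2 called 5 and limma-voom 1, and adjusted over the list alone 2 rose and 1 fell. Over all 11 lists, adjusted over the list alone, 5 rose and 2 fell.

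The rod genes did not fall by equal amounts. Measured against the list's mean, 11 of 24 departed in limma. Nrl lay lower by -0.53 (SE 0.077) and Pde6b by -0.49 (SE 0.082), while Pde6a lay higher by 0.59 (SE 0.090), Rp1 by 0.50 (SE 0.073) and Rcvrn by 0.48 (SE 0.075). The level of the miR-183 cluster was 0.62 and 0.55 in control A and B and -0.66, -0.19 and -0.32 in blue A, B and C of the miRNA libraries; the labels do not say whether mRNA and miRNA libraries with the same letter share RNA.

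A hypothesis was that genes of the photoreceptor cilium, the stalk that carries the outer segment, fell with the rod genes. In a list of 29 tested genes, none in another list, the median log2 fold change was -0.29, 24 were negative and 6 fell over all genes (13 adjusted over the list alone); camera gave p = 9.98e-07 with the preset and p = 0.209 with an estimated correlation. Rp1l1 fell by 1.28, Tulp1 by 1.06, Bbs9 by 0.88, Bbs2 by 0.64, Prom1 by 0.61 and Cep290 by 0.53. The median is in line with the hypothesis and far smaller than the rod median, and since these genes also serve other ciliated cells it may understate a change in rods.

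The fall of rod genes could come from less retina in the blue light samples. Genes of the bipolar, amacrine and horizontal, and ganglion lists pooled had a median log2 fold change of 0.042 (lower quartile -0.15) against -1.53 for rods, which argues against that explanation. Under 3 other scalings the rod median stayed between -1.49 and -1.53. Those scalings put the median of all genes between -0.0051 and 0.041, so they could hardly have moved it. Scaling shifts all genes of a library alike, so it cannot set the rod genes apart from the pooled lists. Fewer rods alone would lower genes active only in rods alike. Yet 11 of 24 departed from the list's mean in limma, with Nrl at -0.53, Pde6b at -0.49 and Pde6a at 0.59. For these genes that argues against fewer rods as the whole source, unless other cells also express them. Open are less transcript per rod, with or without fewer rods, and differences between individual animals of an outbred stock unrelated to light. These tables do not separate them. Animals under blue light were kept in a dark container and controls in natural light. Blue light and housing therefore cannot be told apart here.

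The interferon genes could follow more muscle around the eye in some libraries, or 1 library alone. With the muscle level as a covariate the median was 1.87 (lower quartile 1.43), against 1.76 without it. The muscle level spanned both groups, so this fit could hardly move the median. It speaks only against muscle as the source of the difference between groups. Within each group the interferon level followed the order of the muscle level. Other lists, stroma and orbital gland among them, had that order within groups too. Leaving out 1 library gave medians from 1.20 (without control A) to 2.71 (without control B), which argues against a single library as the whole source. Control A was the lowest of the 5 libraries, blue B lay close to control B, and the adipocyte level had the same order over the 5 libraries as the interferon level and that of 4 other lists, so attached fat, an infection or another difference between animals may contribute and was not tested.

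Moap1 is near 0 in all 3 blue libraries, and a candidate explanation is that its counts moved to the overlapping gene Gm20604. The log2 fold change of their summed counts was -1.45e-06 (SE 0.095), as that explanation needs. Whether the shift lies in the counting or in the transcripts made from the locus stays open.

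Each assay has 10 splits of its 5 libraries into 2 and 3, too few for a share under 0.05. In mRNA 1 of the 10 gave as many genes as the real split, which was the real one, with 421 genes against at most 6 in another; in miRNA it was likewise 1 of 10, with 4 miRNAs against at most 2.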
